A study of Macaca mulatta with 6 samples.

How the data were processed

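Total RNA was purified with a Norgen plasma and serum kit and made into libraries with a QIAGEN UPXome kit, per the labels' protocols, after treatment of the samples with proteinase K, RNase and DNase. Samples were grouped by the fraction in their titles and by the animal named as subject, which gave 2 libraries in each of 3 fractions. Whether the gene counts were collapsed by molecular identifiers was not given in the sources used here, so counts may include PCR copies. Reads were aligned with STAR, per the submitters' processing notes; the version, the genome build, the annotation and the counting step were not given in the sources used here.

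Values of 3 kinds were used. The authors deposited raw counts per gene, with no normalization, for the EV library of each animal, under Ensembl gene identifiers of the rhesus macaque. The columns were matched to the EV libraries because they name the animal and the vesicle fraction. The authors also deposited a table of summed counts per gene and animal, and which libraries were summed was not stated. These sums are given as the authors' values, with no SD. The authors' statistics per library gave input reads as counts, and uniquely and multiply mapped reads as a percent of input reads. Gene counts of the lipoprotein and protein libraries by themselves were not analysed here. The count comparisons between fractions fixed before the data were examined, 4 for genes and 3 for gene lists, therefore had no counts to run on.

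The EV counts were listed for 4642 genes and the sums for 35432. No gene outside the EV table had a summed count. Of its genes, 3584 had a count of 0 in both EV libraries and 236 had 0 in the sums as well. Gene symbols came from a table of gene identifiers and matched 4056 of the 4642 genes and 24186 of the 35432. The EV count exceeded the authors' sum in 19 genes in animal A and 12 in animal B, so the sums do not contain the EV counts exactly as listed. The authors' name for the sums holds the words sense, EV and all, and that for the EV counts names no strand. Both may therefore have been counted differently, which would affect each sum less its EV count and each EV share of a sum. Coordinates and gene lengths were not used, because the annotation at hand belonged to another assembly. Genes with near-identical copies may have lost reads that map to several places, and their counts are uncertain.

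Shares were taken of the total gene count of an EV library, 10397 in animal A and 2842 in animal B, with 95% Clopper-Pearson intervals. The ratio of a gene's shares was given with an exact interval from the conditional binomial distribution. A count of 0 was given a limit of 3 counts. Detection was counted at 1 and at 10 counts, and again after the larger EV library was thinned to the smaller total. Pearson's r was taken on log2(CPM + 1).

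Mapping percentages were compared between fractions by exact two-sided permutation tests over 9 comparisons with Benjamini-Hochberg adjustment. These comparisons were chosen after the files were seen. The libraries of the different fractions come from the same 2 animals, as the subject label states. Animal B had a higher percent of multiply mapped reads than animal A in each of the 3 fractions. Its percent of uniquely mapped reads was higher in the protein fraction alone. Directions in 3 fractions are too few to check the pairing, which rests on the label. A paired sign-flip test was run as an alternative, whose smallest two-sided p is 0.5.

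The 21 gene lists and the rule for named genes were fixed before the data were examined. The rule took genes from each fraction comparison, the 10 genes with the highest mean CPM, and up to 4 members of each list with the highest mean CPM. As fraction comparisons could not be run, the 10 genes were taken from the EV libraries, and unnamed features were limited to a few. Genes named from the authors' sums, and all other named genes outside the rule, were chosen after their values were seen. A gene that the rule would name is not reported here. The comparison with 10000 random lists was also chosen after the files were seen. It used 18 lists, leaving out those of small RNAs, microRNAs and long non-coding RNAs, and drew from 17272 named genes. The rank correlation was planned without stating which genes to use. All genes of the EV table were chosen as the main set after other sets had been tried, and each set is reported.

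The tie test and the ratio intervals were tested on simulated data over 4642 genes. The test of exact ties between both animals gave p under 0.05 in 2 of 100 sets of independent counts, in 25 of 100 sets in which 80% of the smaller count was shared, and in 100 of 100 in which all of it was shared. The simulation with all of the smaller count shared was added after the one at 80%. Intervals for the ratio of shares held the simulated ratio in 1042 of 1076 cases. The list comparison was tested on a separate simulated set of genes, with lists of a single size. That set differed from the named genes used here in size and in the share detected. Its lists drawn at random fell outside the central range in 6 of 200 draws, and enriched lists lay above it in 162 of 200. Alternatives were the count minimum, thinning, denominators without unnamed or leading features, other gene sets for the correlation, weighting by input reads, and leaving out each library. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and seed 1 for random draws.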

Results

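RNA was sequenced from blood plasma of 2 rhesus macaques, animals A and B. The plasma had been separated on a gradient into a lipoprotein fraction, a fraction of extracellular vesicles (EVs, small membrane-bound particles that cells release) and a protein fraction. Each fraction of each animal gave 1 library, so each of the 3 fractions had 2 libraries and the series had 6. The series title places the study in work on early life stress, but the labels gave no stress history for either animal, so no comparison of that kind was made. Gene counts were analysed for the EV libraries and for a column per animal that the authors had summed. Read mapping was analysed for every library.

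Sequencing depth differed widely. The EV libraries held 2615337 input reads in animal A and 913091 in animal B. The lipoprotein libraries held 1194087 and 3612560 reads, and the protein libraries held 1742833 and 1686640. Few of these input reads became gene counts. From 49.53% to 63% of the input reads of a library were neither uniquely nor multiply mapped. The EV library of animal A had a total gene count of 10397, which was 1.64% of its uniquely mapped reads (95% exact binomial interval 1.61% to 1.67%). That of animal B had 2842, or 1.33% (1.28% to 1.38%). A feature without a count could still hold up to 0.0289% of the counts in animal A and up to 0.106% in animal B. These intervals and limits, like those that follow, cover counting error only. They treat counts as independent and are too narrow if counts include PCR copies.

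The first comparison asked whether plasma RNA mapped differently between the gradient fractions. Uniquely mapped reads made up 23.82% ± 0.62 of input reads in the EV fraction (SD, n = 2), 19.87% ± 4.97 in the lipoprotein fraction (SD, n = 2) and 18.90% ± 2.97 in the protein fraction (SD, n = 2). The EV library had a higher share than the lipoprotein library of the same animal in both animals, by 0.88 percentage points in A and 7.03 in B. It also had a higher share than the protein library in both, by 7.46 points in A and 2.38 in B. Multiply mapped reads made up 22.5% ± 6.10 in the EV fraction, 20.5% ± 3.30 in the lipoprotein fraction and 24.8% ± 6.55 in the protein fraction (SD, n = 2 each). Within each fraction the library of animal B had a higher share of multiply mapped reads than that of animal A, with 26.77% against 18.15% for EVs, 22.87% against 18.21% for lipoproteins and 29.47% against 20.20% for proteins. The multiply mapped share of EVs minus proteins was -2.05 points in A and -2.70 in B, and that of lipoproteins minus proteins was -1.99 and -6.60. No fraction difference passed a test, and the design was too small for one to do so. Exact two-sided permutation tests gave p = 0.667 for the uniquely mapped share of EVs against lipoproteins, p = 0.333 against proteins and p = 1 for lipoproteins against proteins. For the multiply mapped share the same exact tests gave p = 1, 0.667 and 0.667. With 2 libraries against 2 the smallest possible p was 0.333, which EVs against proteins reached because both EV libraries had a higher uniquely mapped share than both protein libraries. The comparisons also covered reads mapped neither way, with 53.7% ± 5.47 in EVs, 59.6% ± 1.68 in lipoproteins and 56.3% ± 9.52 in proteins (SD, n = 2 each). For that share, EVs minus lipoproteins was -0.82 points in A and -10.93 in B, with exact permutation p = 0.333. Its other comparisons differed in sign between the animals. Paired by animal, the smallest possible exact p was 0.5, reached by each difference with the same sign in both animals. After Benjamini-Hochberg adjustment over 9 comparisons every unpaired p was 1. The mean difference of 0.965 points in uniquely mapped share between the lipoprotein and protein fractions turned to -2.55 points without the lipoprotein library of animal A. The mean difference in multiply mapped share of 1.92 points between EVs and lipoproteins turned to -2.39 points without the EV library of animal B.

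**Figure D1:**
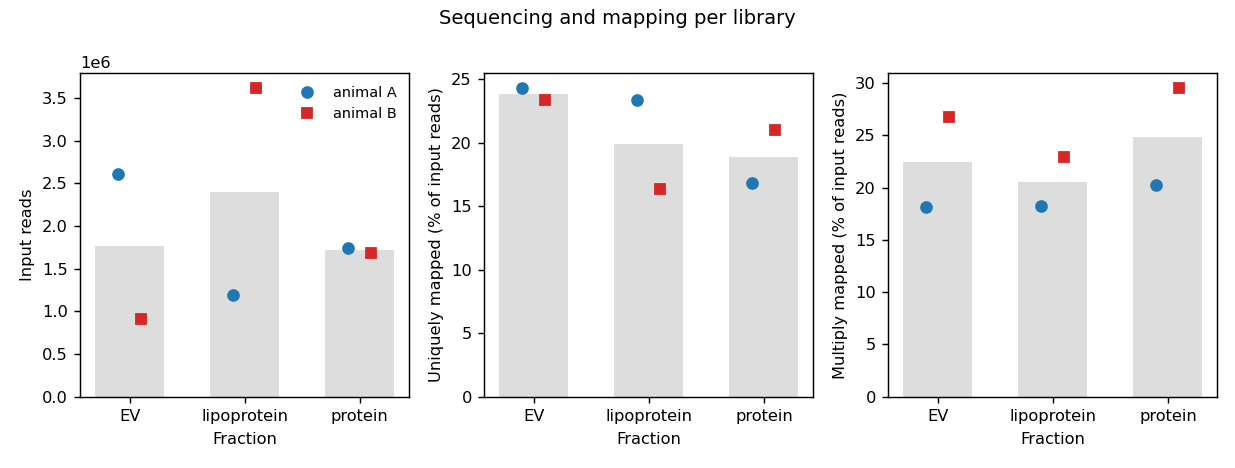
Input reads, and uniquely and multiply mapped reads as a percent of input reads, for each fraction. Grey bars give the mean of 2 libraries, and points give animal A (circles) and animal B (squares). The share of multiply mapped reads was higher in animal B in each fraction.

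The second comparison asked which transcripts the EVs carried and whether the 2 EV libraries shared them. A single feature without a gene symbol, ENSMMUG00000054358, held 35.5% of the counts in animal A (3689 counts, 34.6% to 36.4%) and 48.7% in animal B (1383 counts, 46.8% to 50.5%), or 42.1% ± 9.32 (SD, n = 2). A second unnamed feature, ENSMMUG00000052127, held 11.4% and 10.1%, or 10.7% ± 0.957 (SD, n = 2). The ratio of its shares, A over B, was 1.13 (95% interval 0.996 to 1.30), so no difference was detectable at this depth. Features without a symbol together held 50.03% of the counts in animal A and 67.8% in animal B. The 10 features with the most counts in a library held 77.1% in A and 75.6% in B.

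Named genes with high shares were mostly high in 1 library. FLT3LG, which encodes a cytokine that expands dendritic cells and blood progenitors, had 1017 counts in animal A (9.78%, 9.22% to 10.4%) and 1 count in animal B (0.0352%, 0.000891% to 0.196%). CDH7, a cadherin gene, had 659 counts and 1. RIOX1, a ribosomal oxygenase gene, had 630 counts and 1. Their ratios of shares, A over B, were 278 (49.8 to 10991), 180 (32.2 to 7126) and 172 (30.8 to 6813). In the other direction, TMPRSS6, which encodes a liver serine protease that limits hepcidin, had 4 counts in A and 75 in B. CTNNB1, the gene of beta-catenin, had 17 and 66, and EPG5, an autophagy gene, had 6 and 65. Their ratios of shares, B over A, were 68.6 (25.7 to 258), 14.2 (8.24 to 25.8) and 39.6 (17.3 to 112). The unnamed feature ENSMMUG00000051300 was present in both, with 126 counts in A and 101 in B, and had a share 2.93 times as high in B (2.23 to 3.84). Of 53 features with at least 10 counts in either library, 25 had a higher share in A, 16 a higher share in B and 12 had an interval for the ratio that included 1, with no adjustment for the number of features. These intervals compare 2 libraries and not 2 kinds of animal. A minimum of 10 counts was a lower share in the deeper EV library of A, so it favoured features higher in A.

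**Figure D2:**
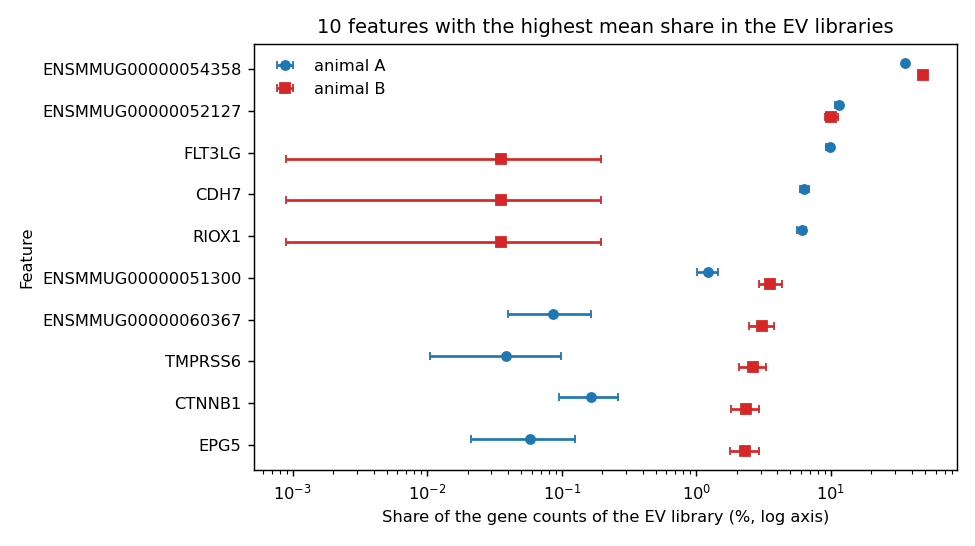
Share of the gene counts (percent, log axis) of the 10 features with the highest mean share in the EV libraries, for animal A (circles) and animal B (squares). Bars are 95% exact binomial intervals. FLT3LG, CDH7 and RIOX1 had 1 count each in animal B.

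Detection was sparse. The EV library of animal A had 796 genes with a count and that of animal B 375, but only 45 and 19 genes had at least 10 counts. When the counts of animal A were thinned to the 2842 of animal B, 333 genes remained detected. Genes with a single count made up 65.3% of detected genes in A and 71.2% in B. A count in both libraries was found for 113 genes, where independent lists would share 64.3 of the 4642 genes listed for the EVs, or 8.42 of the 35432 genes of the summed table, so the size of the excess depends on the genes taken as background. These genes held 80.6% of the counts of A and 85.3% of those of B. Across the 4642 genes, which are not independent replicates, Spearman's rho between the EV libraries was 0.122. It was -0.437 over the 1058 genes with a count in either library and 0.423 over the 113 with a count in both, so its sign depended on the genes included.

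Gene groups that mark blood and liver cells were near the limit of detection in the EV libraries. The 33 hemoglobin and erythroid genes with a matching symbol had 0 counts in both. The hemoglobin genes HBB and HBD matched no symbol, so their counts are unknown. Platelet genes had 1 count in A, from RGS10, and 0 in B. Neutrophil and monocyte genes had 0 in A and 1 in B, from NCF1, and lymphocyte genes had 1 in A, from CD4, and 0 in B. Hepatocyte secreted protein genes had 1 count in A, from the complement gene C3, and 0 in B. Endothelial genes had 1 count in A, from NOS3, the endothelial nitric oxide synthase gene, and 0 in B. Mitochondrially encoded genes, actin cytoskeleton genes, inflammation and interferon genes and nuclear-encoded oxidative phosphorylation genes had 0 counts in both. A count of 0 allows a share of up to 0.0289% in A and 0.106% in B.

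The neuron and ribosomal protein groups had more counts in the EV library of animal A. Neuron genes held 202 counts in A (1.94%, 1.69% to 2.23%) and 3 in B (0.106%, 0.0218% to 0.308%), and DLG4, which encodes the postsynaptic scaffold PSD-95, held 200 of those in A and 2 in B. Cytosolic ribosomal protein genes held 91 counts in A (0.875%, 0.705% to 1.07%) and 1 in B (0.0352%, 0.000891% to 0.196%). These counts came from 4 of the ribosomal protein genes in A and 1 in B, so both groups rested on few genes. Among vesicle tetraspanin, ESCRT and membrane genes, which include proteins used as EV markers, CD9 had 2 counts in each library and RAB35 had 1 in B. Iron and ferritin genes had 3 counts in A and 4 in B, from NCOA4, the receptor for autophagy of ferritin. Glucocorticoid response and stress axis genes had 3 counts in A, 1 each from KLF4, HSD11B2 and DNAJB1, and 0 in B. Glia genes had 4 counts in A, from C1QA, and 0 in B. Translation factor genes had 2 and 1, small and structural non-coding RNA genes 7 and 2, microRNA host features 1 and 0, and replication-dependent histone genes 1 and 0. The list of nuclear and long non-coding RNA genes matched 0 symbols.

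The authors' summed columns held 62794 counts for animal A and 54534 for animal B, over 3635 and 2887 genes. The EV counts were 16.6% of the summed value in A and 5.21% in B, whereas the EV library held 52.6% of the uniquely mapped reads of the animal's libraries in A and 18.4% in B. In the authors' sums ENSMMUG00000054358 again led, with 19608 counts in A and 19111 in B. CDH7 followed with 5798 and 5145. DRD3, the dopamine D3 receptor gene, had summed values of 5139 and 5131 but 7 and 1 counts in the EV libraries. RIOX1 had 3259 and 2633. SHISAL2B had 1734 and 1040, with 179 and 15 counts in the EV libraries. MMP1, an interstitial collagenase gene, had summed values of 520 and 2679, ABHD17A, a depalmitoylase gene, 1141 and 1152, and CPZ, a carboxypeptidase gene, 1220 and 35, each with 0 counts in both EV libraries. Which libraries the sums include was not stated, so these values were not assigned to the lipoprotein or protein fraction.

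In the authors' sums, 18.4% of 17272 named genes had a count in animal A and 14.6% in animal B. Endothelial genes were detected more often, with 10 of 25 in A, where random lists of that size had a median of 5 (central 95% 1 to 9), and 9 of 25 in B (median 4, 1 to 7). Nuclear-encoded oxidative phosphorylation genes were detected less often, with 3 of 66 in A (median 12, 6 to 19) and 3 of 66 in B (median 9, 4 to 16). Replication-dependent histone genes had 1 of 56 in A (median 10, 5 to 16) and 1 of 56 in B (median 8, 3 to 14). Cytosolic ribosomal protein genes had 8 of 83 in A (median 15, 9 to 22) and 7 of 83 in B (median 12, 6 to 19), and neutrophil and monocyte genes 2 of 37 in A (median 7, 2.98 to 12) and 3 of 37 in B (median 5, 2 to 10), so that both lay outside the central range in A alone. The other 13 lists lay within it in both sums. In A the neutrophil and monocyte list was at the border, with 2.5% of random lists at or below its count. Endothelial members with most counts were NOS3 with 9 in A and 8 in B, and VWF, the von Willebrand factor gene, which is also on the platelet list, with 5 and 1. The random lists were not matched for gene length or expression, and the comparison describes these summed columns without replicates. Once the EV counts were taken off, many genes had equal or nearly equal values in both columns, so a like result in A and B cannot be taken as 2 independent results.

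**Figure D3:**
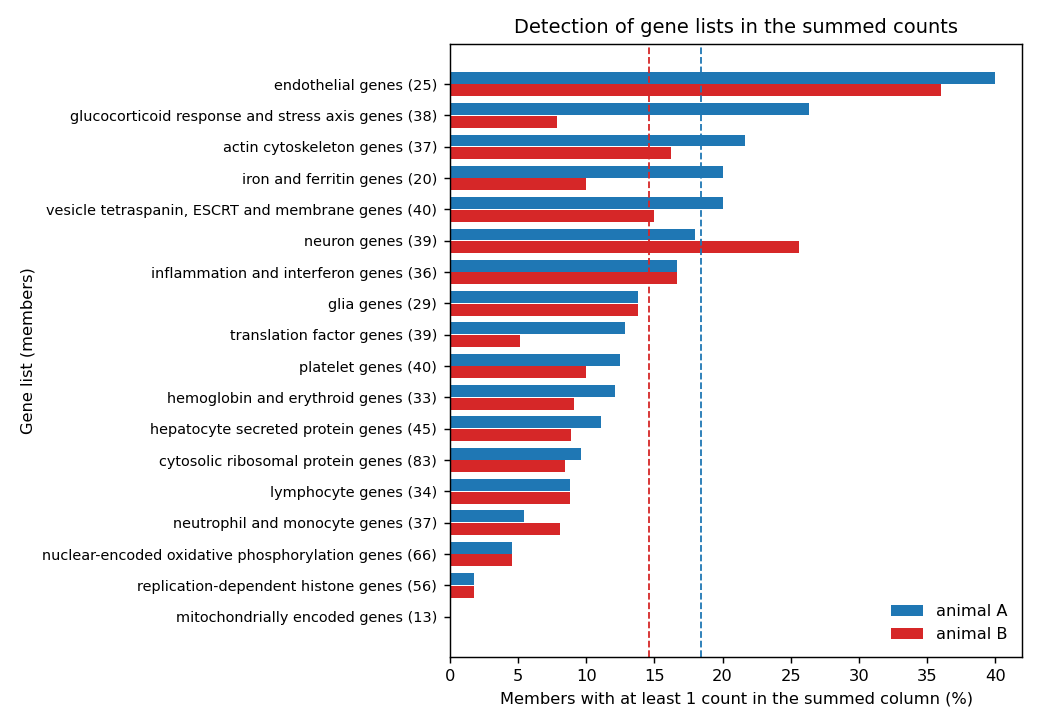
Percent of the members of each gene list with at least 1 count in the authors' summed column of animal A (blue) and animal B (red), with the number of members in parentheses. Dashed lines give the percent of all 17272 named genes with a count, 18.4% in A and 14.6% in B. Endothelial genes lay above these lines in both summed columns, which cannot be taken as independent.

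Summed values were close between the animals for many genes once the EV counts were taken off. The remaining counts came to 52397 in animal A and 51692 in animal B, and the smaller of both values per gene, added up, gave 44482. CDH7 had 5139 and 5144 left, DRD3 5132 and 5130, RIOX1 2629 and 2632, POLRMT 75 and 75, and DLG4 126 and 126. MMP1 and CPZ, which had no EV counts, were not close. Some genes with EV counts were not close either. ENSMMUG00000054358 had 15919 and 17728 left, ENSMMUG00000052127 1878 and 2419, and SHISAL2B 1555 and 1025.

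**Figure D4:**
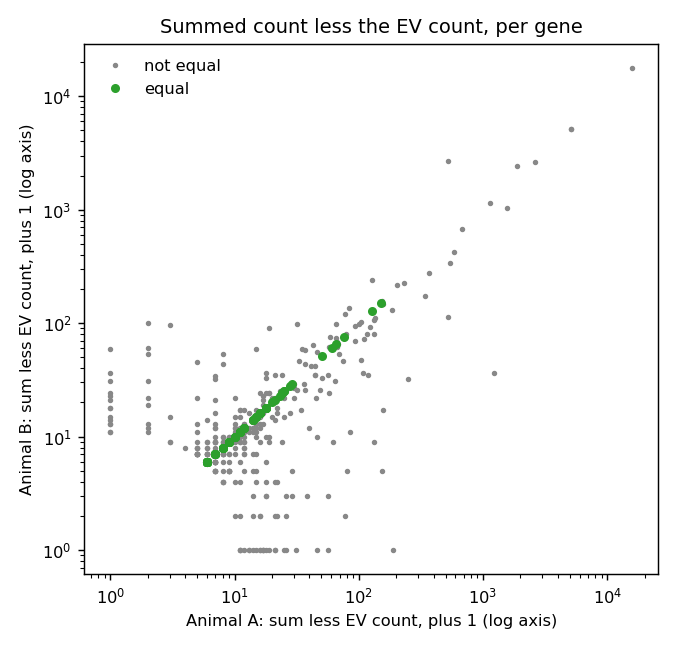
Authors' summed count less the EV count, plus 1, of animal A against animal B (log axes), for genes with at least 10 such counts over both animals and no negative value. Green points are the 94 genes of 415 with exactly equal values.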

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

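The tests of ties, of genes high in 1 EV library and of blood cell transcripts, with their thresholds, were all chosen after the results were seen.

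The animals differed in direction in the comparisons of mapped shares given here. The uniquely mapped share of the lipoprotein library minus that of the protein library was 6.58 percentage points in animal A and -4.65 in animal B. The multiply mapped share of the EV library minus that of the lipoprotein library was -0.06 points in A and 3.9 in B. Each value rests on 1 library per fraction and animal, and the difference between the animals was not tested.

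The authors' sums held counts in genes with 0 counts in both EV libraries, which no fraction comparison used. These genes had 14231 summed counts in animal A, 22.7% of the sum, and 11938 in animal B, 21.9%.

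With the EV count taken off, the authors' sums left nearly equal values in both animals for many genes. Examples were 5139 and 5144 for CDH7, 5132 and 5130 for DRD3, and 126 and 126 for DLG4. The leading feature, ENSMMUG00000054358, was not close, with 15919 and 17728. Of 415 genes with at least 10 such counts over both animals, 94 were exactly equal, where counts drawn independently at equal levels would give at most 42.7 on average (exact one-sided p = 3.37e-15), which argues against equal levels counted independently. A first exact binomial test, one-sided, asked how many genes lay closer together than 95% of independent pairs, and gave 10 of 126 genes at a mean of at least 20 counts (p = 0.101), 10 of 66 at 50 (p = 0.00157) and 6 of 30 at 100 (p = 0.00328); the tie test was chosen after it. The exact tie test gave less in the sums as given, with 58 of 460 against 43.1 (p = 0.00895) at 10 counts, 21 of 256 against 16.1 (p = 0.121) at 20 and 6 of 139 against 5.48 (p = 0.471) at 40, and the EV libraries had 1 of 56 against 3.92. Counts shared by both sums, such as a library added to each, may be the reason for the 94 ties, and which libraries these would be stays open.

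A set of 19 genes had at least 20 counts in the EV library of animal A and 1 or 0 in that of B, with 3234 counts in A, 31.1% of its total, and 7 in B. If counts are independent, the tables argue against a difference in depth alone. Of the 13 features with at least 100 counts in either library, 12 had a ratio of shares whose interval excluded 1. Of these, 10 were higher in A and 2 higher in B. PCR copies would make these intervals too narrow. A minimum of 100 counts was a lower share in the deeper EV library of A, so it favoured features higher in A. Amplification of a few molecules in EV A alone may account for part, because 7 of the 19 genes had 3 or fewer counts left in the sum of A once the EV count was taken off, such as MTX1 with 105 EV counts and a sum of 105. However, 10 of them had 20 or more left and 2 lay between. These fixed limits take no account of the size of the EV count. FLT3LG, with 1017 EV counts and a sum of 1037 in A, was among the 10. The counts left may also be shared by both sums, so this test did not settle it. A difference between the animals cannot be told apart from a difference between libraries, with 1 EV library per animal.

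Many transcripts abundant in blood and liver cells were near 0, with 0 summed counts in both animals for the 18 of 20 looked-up genes that were found. Among them were ALB, ACTB, B2M, PPBP and S100A8. The hemoglobin genes HBB and HBD were not found, so their counts are unknown. However, the hepatocyte list held 84 summed counts in each animal, 78 and 79 of them from CFB. Of the 144 members of the 4 blood cell lists, 14 had a count in the sum of A, below the random range (median 26, 18 to 36). In that of B, 13 had one, at the lower end of the range (median 21, 13 to 29). The sums may not be independent of each other. These members held 29 of the 62794 summed counts in A and 19 of 54534 in B. The members of these lists were therefore not the main source of the summed counts. The test could not decide whether RNA released from blood cells was, because it covered only genes with a symbol. Of the features without one, ENSMMUG00000054358 alone held 31.2% of the summed counts in A and 35.0% in B. Together, features without a symbol held 50.03% of the EV counts in A and 67.8% in B. Loss of multiply mapped reads, which would remove genes with many copies, could still play a part. Were it the only reason, platelet and neutrophil genes, taken as single-copy, would be detected as often as random genes. They had 7 of 77 members in A (median 14, 8 to 21) and 7 of 77 in B (median 11, 6 to 18), below the range in A alone. The value in A goes against it as the only reason and that in B does not, so this test could not decide. Of the 367 members of the 4 blood cell and 4 housekeeping lists, 38 were detected in A (median 67, 54 to 82) and 31 in B (median 53, 41 to 67). This test could not decide whether counts were spread evenly over the genes. Its lists were pooled after their values were seen, and the random lists were not matched for gene length. It followed a test of 18 single lists, with 5 outside the range in A (exact one-sided binomial p = 0.00155) and 3 in B (p = 0.0581) against 0.9 by chance. Of the 5 in A, the neutrophil and monocyte list was at the border, with 2.5% of random lists at or below its count. The binomial test treats the lists as independent, although some share members. A test of the highest counts also came before the pooled test and was set aside, because PCR copies would break it. No biological explanation was tested, because the design names no group that would set these transcripts apart.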

How the results depend on the processing

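The mapping comparisons with their leave-one-out, weighted and paired forms, the EV share of the sums, the number of shared genes, the correlations over genes with a count in either or both libraries and the tie tests were chosen after the data were seen; the other alternatives were planned.

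Of the alternative values, 34 were classed as the same in direction, side of the test's threshold or size, 13 as moved and 10 as reversed. The change in size that counted as moved was not the same for all values. The EV share of the sum in B, from 5.21% to 4.995%, was classed as moved. Spearman's rho of 0.122 against Pearson's r of 0.169 was classed as the same. The cause was not tested except where fewer genes or counts entered. With 1 library left out, the uniquely mapped difference ranged from 0.44 to 7.47 points for EVs minus lipoproteins, 2.82 to 7.02 for EVs minus proteins and -2.55 to 4.48 for lipoproteins minus proteins (negative without lipoprotein A, -2.55, or protein A, -1.135). The multiply mapped difference ranged from -2.39 to 6.23 for EVs minus lipoproteins (negative without EV B, -2.39, or lipoprotein A, -0.41), -7.01 to 2.26 for EVs minus proteins (positive without EV A, 1.935, or protein B, 2.26) and -8.93 to 0.34 for lipoproteins minus proteins (positive without protein B, 0.34). Weighting libraries by input reads turned the uniquely mapped difference of lipoproteins minus proteins to -0.769 and the multiply mapped one of EVs minus lipoproteins to -1.33.

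Pairing by animal left each mean difference as it was, for example 4.92 points for EVs minus proteins, with exact paired p = 0.5 or 1, and changed no call; neither design could pass 0.05.

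Genes detected fell to 45 in EV A and 19 in EV B at 10 counts, and to 333 in EV A after thinning, where shared genes fell to 65 against 26.9 from independent lists. The 10 leading features held 64.8% in A and 38.7% in B among named genes, and 66.3% and 53.8% without the leading feature. The EV share of the sum was 15.5% in A and 4.12% in B without that feature, and 4.995% in B over genes whose EV count did not exceed the sum. Spearman's rho of 0.122 became 0.655 over the 11 genes with 10 counts in both libraries, 0.423 with a count in both and -0.437 with a count in either, where a gene seen in 1 library alone pulls it below 0 by construction. In the exact one-sided tie test, ties numbered 41 of 231 (exact p = 3.15e-09) at 20 counts and 14 of 126 (p = 0.000369) at 40.

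Not run, for lack of counts per library outside the EV fraction: all alternatives for genes and gene lists between fractions (other tools, normalizations, filters, pairing, left-out libraries). At this depth a count of 0 allows a share of up to 0.0289% of the EV counts in A and 0.106% in B.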

Other observations

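The comparisons of the authors' sums, and of the EV libraries with them, were chosen after the data were seen, as were the genes named here except CFB, POMC and ENSMMUG00000051300.

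Several genes had nearly all of the authors' summed count of an animal in its EV library. In animal A, USP4 had 37 EV counts and a sum of 37, MTX1 105 and 105, and SMOC1 and SF3B3 22 and 22 each, with 0 in the EV library and the sum of animal B. In animal B, IL22RA1, an interleukin 22 receptor gene, had 20 and 20, and GDF6, a growth factor gene, 12 and 12, with 0 in both values of animal A. Among genes with at least 10 EV counts, 9 of 45 in A and 2 of 19 in B equalled the sum. Other genes had counts in both EV libraries, among them CCRL2, a chemokine receptor-like gene, with 32 in A and 23 in B, KCNT1, a potassium channel gene, with 26 and 43, ADRA1B, the alpha-1B adrenergic receptor gene, with 11 and 11, and TBR1, a cortical neuron transcription factor gene, with 20 and 8.

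Among hepatocyte secreted protein genes, CFB, the complement factor B gene, held most of the authors' summed counts, with 78 of 84 in animal A and 79 of 84 in animal B, and had 0 EV counts. In the glucocorticoid response and stress axis list, 10 of 38 genes had a summed count in A and 3 of 38 in B, both within the range of random lists. POMC, the precursor gene of the stress hormone ACTH, had 2 and 1. MMP1 and CPZ differed between the sums, with 520 and 2679 for MMP1 and 1220 and 35 for CPZ. PDE1B, a phosphodiesterase gene, had 586 and 419 with 0 EV counts. ENSMMUG00000051300, with 126 and 101 EV counts, was listed at 0 in both sums.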
